A study of Homo sapiens with 4 samples.

How the data were processed

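Gene expression in a pair of clones of HCT116, a human colorectal cancer cell line, was compared on 4 cDNA arrays with 2 colours each. Per the labels, each array held labelled RNA of HCT116-Clone2, a clone resistant to X-rays, and of HCT116-Clone10, a control clone whose response to X-rays resembles that of the parental cells. Neither clone was irradiated. RNA was taken from different batches of cells and pooled before labelling, and the sources used here do not state whether all 4 arrays received the same pool. The clone HCT116-Clone2 was labelled with Cy5 on arrays 1 and 2 and with Cy3 on arrays 3 and 4.

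Per the labels, total RNA was extracted with RNeasy columns, the arrays were scanned with ScanArray Express, and spots were quantified in QuantArray version 3.0. Per the labels, the authors then used Normaliser2, a spreadsheet macro. It subtracted the background within each subarray, normalised the spots of each subarray by regression, and gave the log2 ratio of both channels. The labels also state that spots were removed when their signal was under 2.5 times the subarray background, when they were under 5% spot intensity, or when they lay on streaks or damage. The deposited table used here held a log2 ratio for each of 19200 spots on each of the 4 arrays, with 0 empty cells, and it gave no intensity. Spots that had failed the authors' filter could therefore not be told from the others, and dim spots were not left out. The medians of the deposited log2 ratios were 0.00937, 0.0294, 0.00542 and -0.00168 on arrays 1 to 4, so the values were taken as centred and used as deposited. The scale (log2) is the one the labels give.

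The channel in the numerator of the ratio is not given in the sources used here. The labels list HCT116-Clone2 under the same channel on every array, whichever dye it carried. If the ratio was taken by listed channel, the columns would already be oriented to the same cells. A rule fixed before the data were examined was used for the sign. Arrays of opposite labelling correlated below 0 (Pearson r from -0.0834 to -0.028 over spots as deposited), so the columns were read as dye ratios and the sign of arrays 3 and 4 was turned. A positive turned ratio means a ratio above 0 with HCT116-Clone2 in Cy5. It stands for more transcript in HCT116-Clone2 if Cy5 is the numerator and for more in HCT116-Clone10 if Cy3 is. The channel listing allows that the deposited columns were already oriented to the same cells on every array, and the weak correlations do not rule it out. In that case the turned ratio measures a dye effect and no difference between the clones.

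Of the 19200 probes, 10914 had 1 gene symbol in the platform annotation, 1435 had several and 6851 had none. Among those with 1 symbol, 10882 were found in the RefSeq gene table of assembly GRCh38.p14 through their gene identifier, and 0 symbols changed. No gene was named from a probe with several symbols. Spots of one accession and symbol were averaged, which left 18828 features. For tests of genes and gene lists, all features of a gene were averaged on each array, which left 7498 genes.

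Features and genes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a term for the clone and a term for the dye, over all 4 arrays. This leaves 2 residual degrees of freedom, to which the empirical Bayes step added 2.74 for features and 2.81 for genes. Tests were two-sided, with Benjamini-Hochberg adjustment over all features or all genes and a threshold of 0.05. A feature needed values on at least 3 arrays, which all features had. With both terms in the fit, the p-values, SEs and intervals measure the spread between arrays of the same labelling, which may be technical. They hold neither the difference between the 2 labellings nor the spread between cultures. Each side is 1 clone. For arrays, their number limits the precision. On simulated data of 18828 features with the spread of these arrays, the fit called 0 of 50 features changed 1.5-fold, 2 of 50 changed 2-fold, 39 of 50 changed 4-fold and 47 of 50 changed 8-fold, with 5 false calls. The changes were simulated together, which eases the adjusted threshold, and with no effect of place or batch. Of the unchanged simulated features 4.7% had an unadjusted p below 0.05 in limma, against 10.5% of all real features. The simulation therefore differs from the real arrays, and its shares of called features may not hold for them.

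The shift of 27 gene lists fixed before the data were examined was tested with cameraPR on the moderated t of the 7498 genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and with camera's estimated correlation as an alternative. On simulated lists of 20 genes, a shift of 0.1 on the log2 scale gave p below the threshold of 0.05 in 15 of 20 lists, and a shift of 0.2 in 19 of 20. These p were not adjusted over lists, and the simulated genes were independent, with no effect of dye or place. In the real data a mean of 0.096 over 26 genes of DNA replication gave an unadjusted p of 0.214 in cameraPR. The simulation therefore does not exclude shifts of that size in the real lists. Genes of the autosomes and of chromosome X were tested in the same way, 1 list per chromosome, for chromosomes with at least 20 genes. Chromosome Y was left out.

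The rule for named genes was also fixed beforehand. It took the 12 genes with the largest ratios per direction among those past the threshold, and called members of each list. If fewer than 10 genes passed, it took the 10 genes per direction with the smallest p, named as not passing. Features with 1 gene symbol and the same sign on all 4 arrays were eligible, and asking for no common sign would have changed 1 gene. The rule also took members of the mismatch repair list and, from another pathway, CDKN1A and MDM2 where measured. Of the 27 lists, 26 are reported, and 1 list and some genes of the rule are not reported here.

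Alternatives fixed beforehand were a fit with no dye term, median centring of each array, centring with scaling, robust empirical Bayes, separate spots, leaving out each array in turn, a fold threshold of 1.5, the first feature of a gene in file order, an estimated correlation, and ranks in place of t. Alternatives chosen after seeing the data were removal of the local median (each spot minus the median of the other spots in a window of 5 by 5 spots in its subarray), leaving out the first of the 4 columns of subarrays, the picked feature of a gene alone, and turning no array. Counts at an unadjusted p and signs of list members with no array turned were also added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.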

Results

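The study compared transcript levels of 2 unirradiated clones of HCT116, a human colorectal cancer line that is deficient in mismatch repair. HCT116-Clone2 is resistant to X-rays, and HCT116-Clone10 is a control clone with a response like that of the parental cells. The comparison asks which transcripts differ between the resistant and the control clone before any radiation is given. The data are log2 ratios of both clones for 19200 spots on each of 4 arrays, 2 arrays per dye orientation. The SD of the log2 ratio over spots was 0.438, 0.466, 0.566 and 0.528 on arrays 1 to 4, and 3.56%, 4.91%, 8.03% and 6.4% of spots were over 2-fold from 0. Ratios are given below with arrays 3 and 4 turned in sign. A positive value stands for a ratio above 0 with HCT116-Clone2 in Cy5, and whether that is more transcript in HCT116-Clone2 or in HCT116-Clone10 is not settled, because the numerator of the ratio is not given in the sources used here. The labels list HCT116-Clone2 under the same channel on every array, so the columns may already be oriented to the cells. If they were, the turned ratios measure dye and not clone.

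Among spots with a positive turned ratio and the smallest p, the largest ratio was that of GRM5, a metabotropic glutamate receptor, at 3.44 on the log2 scale (SE 0.39, 95% interval 2.43 to 4.45, n = 4 arrays), a difference of 10.8-fold. It was followed by FGG, the gamma chain of fibrinogen, at 1.92 (SE 0.22), CASTOR1, an arginine sensor of the mTORC1 pathway, at 1.49 (SE 0.17), and TDO2, a dioxygenase that opens tryptophan catabolism, at 1.38 (SE 0.13). CEP170, a centrosomal protein, had a ratio of 1.26 (SE 0.14), SNX33, a sorting nexin, of 1.14 (SE 0.18), and ELF1, an ETS-family transcription factor, of 1.11 (SE 0.14). The ratios of ACSS3, a mitochondrial acyl-CoA synthetase, FNBP1L, a membrane-bending regulator of actin assembly, and KATNBL1, a regulator of the microtubule-severing protein katanin, were 1.01, 0.88 and 0.84.

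Among spots with a negative turned ratio and the smallest p, the largest was that of ADARB1, an adenosine deaminase that edits RNA, at -2.18 (SE 0.25, 95% interval -2.85 to -1.52), a difference of 4.54-fold. GNG12, a gamma subunit of G proteins, was at -1.62 (SE 0.23), EPB41L1, a protein of the membrane skeleton, at -1.51 (SE 0.13), and MAP3K5, the stress-activated kinase ASK1, at -1.22 (SE 0.16). PTPRM, a receptor tyrosine phosphatase, was at -1.19 (SE 0.12), NR4A3, an orphan nuclear receptor, at -1.04 (SE 0.13), and AGBL5, a carboxypeptidase acting on tubulin, at -1.03 (SE 0.15). RFLNB, an organiser of actin filaments, DLL1, a Notch ligand, and CHRM1, a muscarinic acetylcholine receptor, were at -1.02, -1.01 and -0.86. Some turned ratios were uneven between the orientations, which the dye term took up, so their SE does not hold this unevenness. On arrays 1 and 2 against arrays 3 and 4, DLL1 was at -0.15 and -0.29 against -1.51 and -2.09, and NR4A3 at -0.21 and -0.60 against -1.70 and -1.64. MAP3K5 was at -0.57 and -0.91 against -2.01 and -1.39, and TDO2 at 1.76 and 2.11 against 0.89 and 0.77. With no array turned, the means of the 20 named spots ran from -0.61 for GRM5 to 0.79 for DLL1, with CASTOR1 at 0.008 and ADARB1 at 0.07, so their choice, order and signs rest on the turning.

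**Figure D1:**
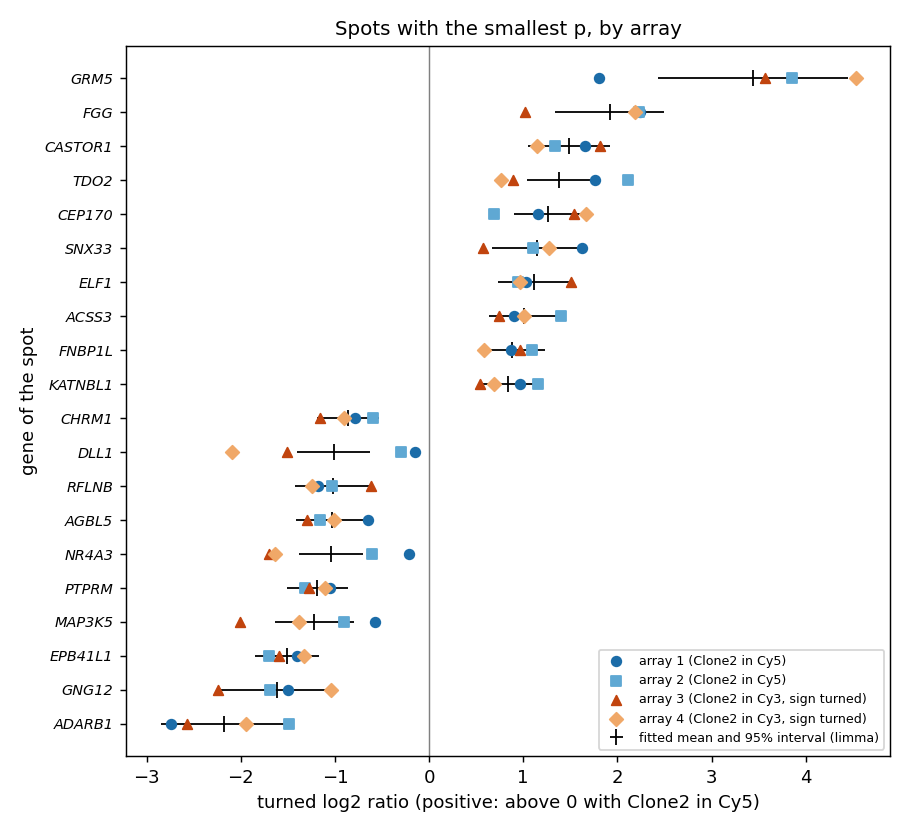
Turned log2 ratio on each of the 4 arrays (points) for the spots of the 20 named genes, with the limma mean and its 95% interval (vertical tick and line). All 4 arrays lie on one side of 0 for each spot because the rule asked for it; GRM5 is farthest from 0 at 3.44 and ADARB1 is the lowest at -2.18, and 0 of these spots passed the adjusted threshold.

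None of these 20 genes passed the test. The adjusted p of each was 0.463 in limma with Benjamini-Hochberg adjustment over 18828 features, which was also the smallest of all features, and 0 features were called. At an unadjusted p below 0.05 there were 1981 features, 966 positive and 1015 negative, where 941 are expected by chance. Their number was 1254 without array 1, 996 without array 2, 1988 without array 3 and 2311 without array 4. Without array 1 or 2 the residual comes from arrays 3 and 4 alone, and without array 3 or 4 from arrays 1 and 2. These counts therefore do not show which arrays carry the ratios. At gene level 0 of 7498 genes were called (smallest adjusted p = 0.465). A mean of at least 2-fold with the same sign on all 4 arrays was found for 64 features, 21 positive and 43 negative. Over all features, 18.9% had one sign on all 4 arrays, where chance gives 12.5% if the arrays are independent. Arrays of one orientation correlated (r = 0.149 and 0.184), which raises that share with no clone difference.

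Several of the named ratios were those of 1 spot among several features of the gene. For 8 of the 20 genes the array held 12 further features, of which 5 had the sign of the named spot and 0 had an unadjusted p below 0.05. Averaged over its features, the ratio was 0.18 for FGG (5 features), 0.67 for CASTOR1 (2 features), -0.55 for GNG12 (3 features), -0.57 for PTPRM (2 features), -0.49 for RFLNB (2 features), -0.61 for AGBL5 (2 features), and -0.85 for both EPB41L1 and NR4A3 (2 features each). After removal of the local median, the gene means of PTPRM, RFLNB, AGBL5 and EPB41L1 were -0.31, -0.20, -0.25 and -0.45, and without array 2 that of NR4A3 was -0.55. The spots of GRM5, CASTOR1 and ACSS3 were neighbours on the array. Other named spots also lay among spots of their own sign, with neighbour medians of 0.57 around TDO2, -0.54 around GNG12, -0.53 around EPB41L1 and -0.51 around MAP3K5. Of the named spots, 10 lay in the first of the 4 columns of subarrays, 7 of them negative. That column held 24.9% of all features and 43 of the 64 features with at least 2-fold and a common sign, 35 of them negative.

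**Figure D2:**
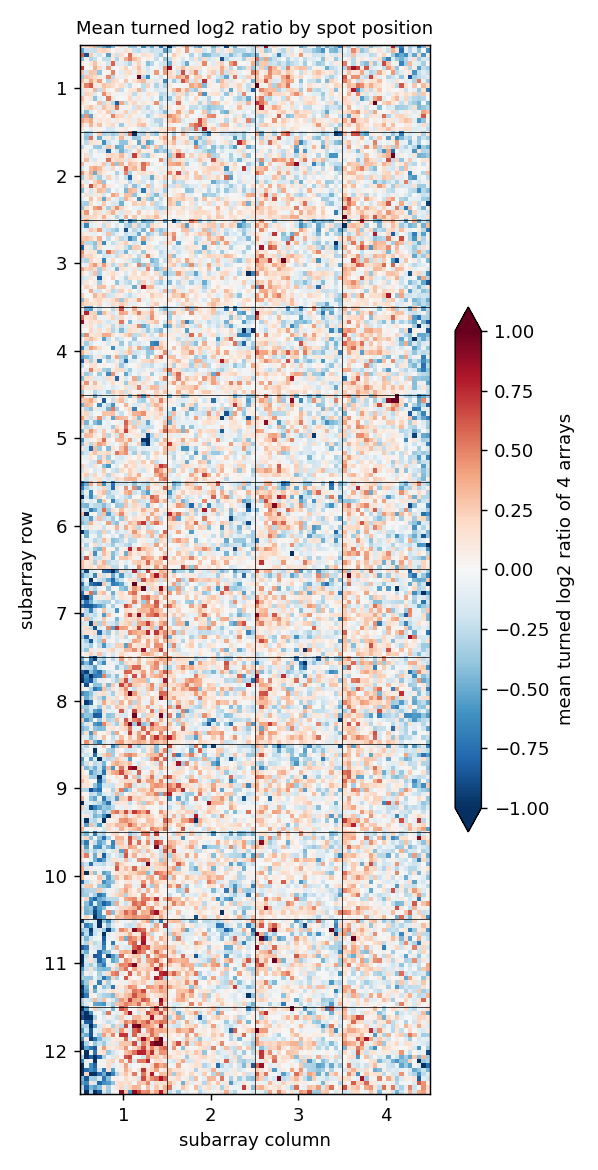
Mean turned log2 ratio of the 4 arrays (colour, from -1 to 1) at each spot's place, with 12 rows and 4 columns of subarrays marked by lines. Negative spots gather along the outer edge of the first column and positive spots beside them in its lower rows; 13.7% of features in that column had an unadjusted p below 0.05, against 7.74%, 9.14% and 11.5% in columns 2 to 4.

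Arrays resembled each other little. Over spots as deposited, Pearson's r was 0.149 between arrays 1 and 2 and 0.184 between arrays 3 and 4 (Spearman's rho 0.172 and 0.222). Between arrays of opposite labelling r was -0.028, -0.0367, -0.0834 and -0.0781 (rho -0.0162, -0.0235, -0.0641 and -0.0637). These correlations run across spots, which are not independent replicates. Turning arrays 3 and 4 therefore rests on a weak negative relation. With these arrays turned, the mean r between opposite orientations was 0.0565, and 0.0152 after removal of the local median. Most of that relation was thus lost with the local median. With no array turned the count of called features was also 0, with 1632 at an unadjusted p below 0.05. The dye term of the fit, which is the mean with no array turned, had 0 called features and a smallest adjusted p of 0.569. Labelling orientation and any slide or labelling batch cannot be told apart here, since the slides are numbered in sequence within each orientation.

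Genes of mismatch repair, which is defective in HCT116, and CDKN1A were named in advance. MSH6, a partner in mismatch recognition, had a ratio of 0.80 (SE 0.18, 95% interval 0.34 to 1.27, n = 4 arrays), a difference of 1.75-fold. Its adjusted p was 0.465 over all genes, and 0.0283 adjusted over the list alone. The turned values of MSH6 were 0.42, -0.20, 1.83 and 1.17 on arrays 1 to 4, positive on 3 of 4. Its SE does not hold the unevenness between the orientations. Its p adjusted over the list alone was 0.159 with no dye term, 0.163 without array 1 and 0.106 without array 3, each above the threshold. With no array turned the mean of MSH6 was -0.70 (adjusted p = 0.569 in limma over features), of the opposite sign. PMS1, MSH3 and PMS2, other members of the mismatch repair complexes, were at 0.08 (SE 0.12), 0.07 (SE 0.25) and 0.03 (SE 0.12). Leaving out 1 array moved PMS1 to between 0.0097 and 0.16 and turned the sign of MSH3 (-0.25 without array 2) and PMS2 (-0.043 without array 4). CDKN1A, the cell-cycle inhibitor p21, was at 0.19 (95% interval -0.13 to 0.51, adjusted p = 0.602 in limma), and at 0.11 without array 4. MDM2, also named in advance, had no feature with 1 gene symbol among the probes used here.

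None of the 27 gene lists passed the test against the other genes (cameraPR, smallest adjusted p = 0.757; smallest adjusted p = 0.976 with an estimated correlation). Of 1040 distinct genes in the lists 544 were measured, of which 0 were called over all genes and 1, MSH6, adjusted over the list alone. At an unadjusted p below 0.05 there were 52, or 9.56%, where 27.2 are expected by chance; the share over all genes was 10.1%. In the 26 lists reported, medians ran from -0.10 for base and nucleotide excision repair to 0.0788 for mismatch repair, and removal of the local median changed the sign of the test for 7 lists. With no array turned, 15 of these 26 lists had the other majority of signs, so the counts of positive and negative members hold only for the turned ratios. Median, mean and test differed in sign for 7 lists, namely double-strand break repair, apoptosis regulators, mitosis, antioxidant genes, heat shock genes, the NF-kB list and the goblet and enteroendocrine markers.

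In the DNA repair lists no member was called over all genes. Of 18 double-strand break repair genes 11 were positive and 7 negative, with a median of 0.06; PRKDC, the catalytic subunit of DNA-dependent protein kinase, was at -0.82 (SE 0.23) and its partner XRCC5, or Ku80, at -0.34 (SE 0.17), while RAD52 was at 0.36 and RAD1 at 0.32. All 4 measured mismatch repair genes were positive, but 3 of 4 with centring and scaling of the arrays, where PMS2 turned negative, and 0 of 4 with no array turned (list adjusted p = 0.757). Of 20 base and nucleotide excision repair genes 13 were negative, among them the helicase ERCC2 at -0.34. That list also held MGMT, an alkyltransferase that repairs bases by direct reversal, at -0.33. Apoptosis regulators were split evenly, 8 positive and 8 negative, with BCL2 at -0.43 and the inhibitor XIAP at 0.19.

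Proliferation and stress lists were also mixed. Of 26 genes of DNA replication and the G1/S step 14 were positive, with ORC4, a subunit of the origin recognition complex, at 0.61 and the helicase subunit MCM7 at -0.34. Of 23 genes of mitosis and G2/M 12 were positive, or 11 with centring and scaling, with the phosphatase CDC25B at 0.31 and the cyclin CCNB2 at -0.38. Of 6 histone genes 4 were positive (median 0.07). Of 34 antioxidant and glutathione genes 18 were positive; GCLM, the modifier subunit of glutamate-cysteine ligase, was at -0.85 (SE 0.22) and the catalytic subunit GCLC at 0.20 (SE 0.11). Of 5 metallothioneins 4 were negative, with MT2A at -0.20. Of 26 heat shock genes and chaperones 14 were positive, with HSPA1A at -0.44 and HSPH1 at 0.49. Of 21 proteasome genes 13 were positive, with PSMD5 at 0.39 and PSMD14 at -0.39.

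Lists of abundant and metabolic transcripts had more negative than positive members, as they did with centring and with scaling of the arrays. With no array turned this held for the ribosomal proteins, 27 of 40, and not for the other lists, with 17 of 39, 7 of 23 and 5 of 17 negative for oxidative phosphorylation, glycolysis and cholesterol synthesis. The counts with arrays 3 and 4 turned were 25 of 40 for cytosolic ribosomal proteins, 25 of 39 for oxidative phosphorylation, 15 of 23 for glycolysis and hypoxia response, and 12 of 17 for cholesterol and fatty acid synthesis, each at an adjusted p of 0.757 in cameraPR. RPL30, a protein of the large ribosomal subunit, was at -0.68 (SE 0.14), SDHD, a subunit of succinate dehydrogenase, at -0.56 (SE 0.22) but SDHA of the same enzyme at 0.28 (SE 0.11) and NDUFB2, of respiratory complex I, at 0.51 (SE 0.22), and the glycolytic enzymes PFKL and ENO1 at -0.46 and -0.34. GAPDH, also glycolytic, was at -0.36 (SE 0.13) over 6 features. MVK, mevalonate kinase, was at -0.63 (SE 0.14) and the fatty acid desaturase FADS2 at -0.54 (SE 0.13).

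Among signalling and structural lists, 14 of 29 growth factor and early response genes were positive, with the receptors ERBB3 at -0.87 (SE 0.29), FGFR3 at -0.58 and EGFR at 0.65 (SE 0.29). Of 21 Wnt pathway genes 9 were positive, with SOX9 at 0.35 and ID2 at -0.39. Of 19 genes of the NF-kB list 9 were positive, with BCL3 at 0.60 and the kinase CHUK at -0.42. Of 23 interferon-stimulated genes 12 were positive, with the thiol reductase IFI30 at -0.55 and B2M, the light chain of MHC class I, at 0.29. Of 13 epithelial junction and keratin genes 9 were positive, or 3 with no array turned, with the adhesion molecule EPCAM at 0.38 and the desmosomal protein PKP3 at -0.46. Of 33 mesenchymal and matrix genes 16 were positive, with N-cadherin (CDH2) at 0.48. Of 28 genes of the tubulin and actin cytoskeleton 12 were positive, with the capping protein CAPZA1 at 0.89 (SE 0.25) and ARPC5, of the Arp2/3 complex, at -0.50.

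Markers of other cell types were tested as a background, though goblet and enteroendocrine cells belong to the intestinal epithelium and are not foreign to a colorectal line. Positive members numbered 8 of 14 for leukocyte markers, 6 of 20 for fibroblast markers, 6 of 16 for endothelial and erythroid markers, and 3 of 6 for goblet and enteroendocrine markers, with list medians of 0.04, -0.05, -0.05 and 0.02. Single members reached sizes like those of the other lists, such as the endothelial receptor TEK at -0.65 (SE 0.13) and the matrix protein POSTN at -0.69 (SE 0.18). Their adjusted p in cameraPR was 0.996, 0.757, 0.757 and 0.996.

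**Figure D3:**
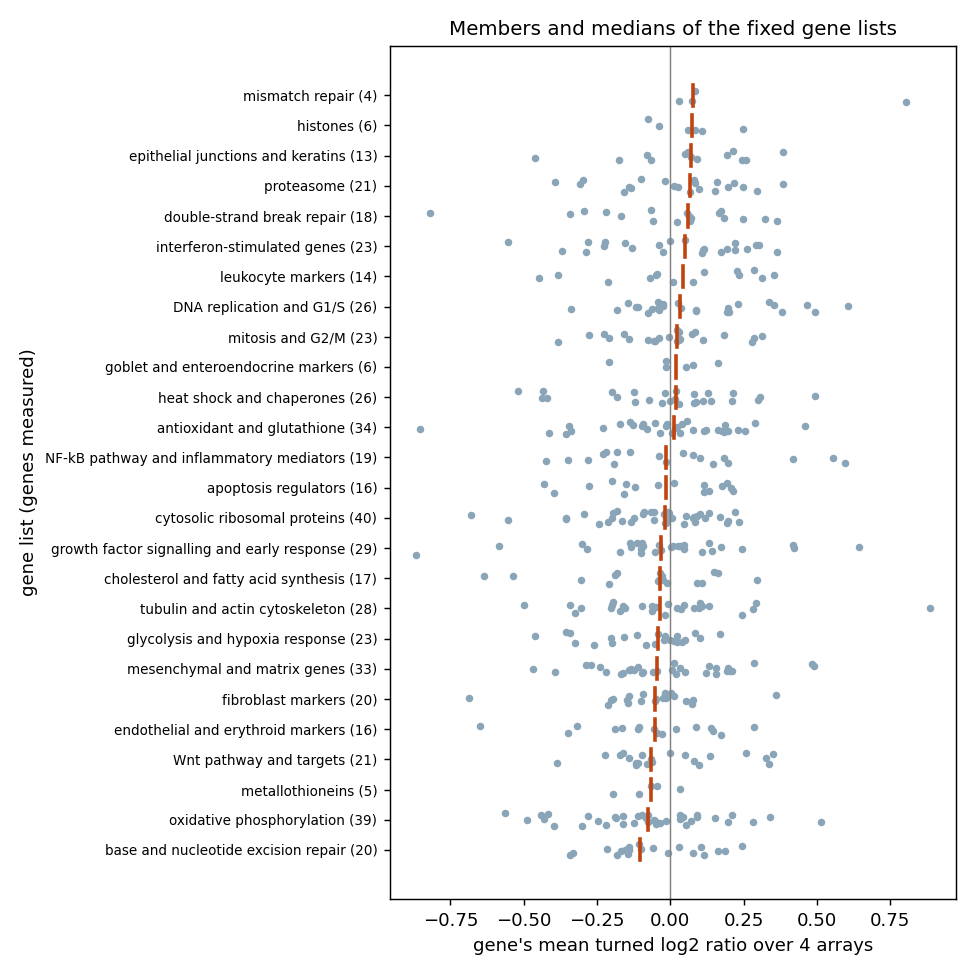
Mean turned log2 ratio of each measured gene (points) in 26 lists, with each list's median (orange line) and the number of genes measured in brackets. Medians stay between -0.104 and 0.0788, while single members such as CAPZA1 at 0.89 and ERBB3 at -0.87 lie far from them, in marker lists of other cell types too.

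The clones could differ in chromosome content, so the genes of each chromosome were compared with all others. Over 23 chromosomes with 93 to 779 genes, 0 passed the threshold (cameraPR, smallest adjusted p = 0.911; smallest adjusted p = 0.79 with an estimated correlation). Chromosome medians ran from -0.06 on chromosome 22 to 0.03 on chromosome 13. Chromosome 19 had the smallest unadjusted p of 0.0766, with a median of -0.04 over 412 genes, and chromosome 4 had a median of 0.03 over 315 genes.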

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

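Of the tests in this part, the one on 2 spots of an accession across orientations was set before its result was seen; the other tests were chosen after. In 2 of 31 groups of 4 arrays tested, 1 array stood apart from the others by Dixon's ratio, where chance gives 1.55. For FGG the ratio was 0.952, because array 3 was at 1.02 and the other arrays lay between 2.18 and 2.24. For ELF1 it was 0.846, because array 3 was at 1.51 and the others lay between 0.94 and 1.03.

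More features than chance gives had an unadjusted p below 0.05, namely 1981 against 941. Removal of the local median still gave 1558 features, 1073 of them among the 1981. Place effects that a window of 5 by 5 spots takes out are therefore not the whole cause, and finer patterns of place were not tested. The count was 996 without array 2 and 2311 without array 4, with the residual then set by 1 pair of arrays alone. The 4 arrays allow 3 splits into pairs, too few for a share under 0.05. Only 1 of them gave as many, the real one, and the highest other gave 673. In the other splits any difference between the labellings, of clone or of batch, goes into the residual and lowers the count. Their counts are therefore no measure of chance for the real split. A labelling or slide batch tied to dye orientation and differences between the clones' transcripts were weighed next. The turned means of both orientations correlated at r = 0.0941 as deposited (95% bootstrap interval 0.0443 to 0.146) and at r = 0.0237 after removal of the local median (-0.000189 to 0.0538). Different spots of one accession correlated at 0.198 over 249 pairs (one-sided permutation p = 0.0011) for the clone term and at 0.184 for the dye term. After removal of the local median these were 0.126 (permutation p = 0.022) and 0.0641. As deposited, the agreement is therefore not specific to the clone term. With each spot taken from another orientation, r was -0.00516 (permutation p = 0.557), and 0.022 (permutation p = 0.312) after that removal. The bound set beforehand against transcript differences was r at or below 0, which -0.00516 met. It met it narrowly and lay within the spread of permuted pairs, so transcript differences cannot be told apart from a batch here.

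The spots of GRM5, CASTOR1 and ACSS3 lie side by side and share a positive ratio, at 3.44, 1.49 and 1.01. Signal of the GRM5 spot may have reached its neighbours. Its other 6 neighbours were all positive, with a median of 0.25, at the 94.2 percentile of such medians over all spots, just short of the bound of 95 set for that explanation. With CASTOR1 and ACSS3 counted, the median of all 8 neighbours was 0.40, at the 99.2 percentile; these 2 were left out after that value was seen, and the patch is not particular to GRM5, since the neighbours of TDO2 had a median of 0.57, at the 99.9 percentile. After removal of the local median CASTOR1 was at 1.29 and ACSS3 at 0.82. A few bright spots hardly move the median of a window, so this removal does not bear on spill. The other CASTOR1 feature, elsewhere on the array, was at -0.14. Spill and a difference of these transcripts cannot be told apart here.

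For 8 named genes the array holds further features, and these argue against a difference of the whole gene's transcripts at the size of the named spot. Turned to the sign of that spot, the 12 other features had a median of -0.04 (SD 0.353), against a smallest named size of 1.02. Of them 5 had the sign of the named spot (exact binomial p = 0.774). The named spots were picked for a small p, and a difference in 1 transcript form or an error of 1 spot stays open and was not tested.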

How the results depend on the processing

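Counts of called features, gene lists and chromosomes were 0 in every alternative run, with smallest adjusted p of features from 0.223 (no dye term) to 0.827 (without array 2). The unadjusted count and its alternatives, removal of the local median, leaving out the first column of subarrays, the picked feature and turning no array were chosen after seeing the data. The count of 1981 ranged from 996 to 2311 when 1 array was left out; of the 100 features with the smallest p, 24 to 37 were among the 100 smallest then. Mean r between arrays of one orientation moved from 0.167 to 0.107 after removal of the local median, and between opposite orientations from 0.0565 to 0.0152, and to 0.0321 without the first column; the cause was not tested. By gene mean, CASTOR1 went from 0.67 to -0.14 with the first feature in file order, PTPRM from -0.57 to 0.0495 with the first feature and without the first column, and RFLNB from -0.49 to 0.0306 without that column, since each then rests on another feature. AGBL5 went from -0.61 to -0.18 with the first feature, while for FGG, EPB41L1, GNG12, NR4A3 and RFLNB the first feature was the named spot itself. PMS2 went from 0.028 to -0.028 when centred and scaled and to 0.32 after removal of the local median, and ranged from -0.043 to 0.10 without 1 array; MSH3 then ranged from -0.25 to 0.40, PMS1 from 0.0097 to 0.16, CDKN1A from 0.11 to 0.27 and NR4A3 from -1.16 to -0.55. After removal of the local median the gene means of EPB41L1, PTPRM, AGBL5 and RFLNB were -0.45, -0.31, -0.25 and -0.20, against -0.85, -0.57, -0.61 and -0.49 as deposited; the cause was not tested. The mismatch repair list came nearest to a call after removal of the local median (adjusted p = 0.0581; 0.216 with no array turned, where its sign was negative, and 0.549 to 0.976 in the other alternatives). Features measured on all 4 arrays are all features, so that alternative changed nothing. Each array held both clones, so each ratio is already a paired difference within an array. The arrays form 1 group, and no further pairing was made. Signal over background was not known per spot, so its limit on dim spots could not be set.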

Other observations

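The tests in this part were chosen after the results were seen. Genes of the ribosomal, oxidative phosphorylation, and glycolysis and hypoxia response lists were more often negative than positive when pooled. Many of them are among the most abundant transcripts of most cells. The last list also holds hypoxia response genes such as VEGFA and EPAS1, so the pool is not made of abundant transcripts alone. Of 102 genes, 65 were negative and 37 positive, with a median of -0.05; with no array turned, 51 were negative and 51 positive, with a median of -0.000975. One hypothesis is that abundant transcripts were measured lower as a class. The pooled lists gave a two-sided p of 0.0434 against all other genes with a preset correlation, and p = 0.0997 with an estimated correlation. The p was 0.0271 after removal of the local median, 0.0417 with median centring and 0.0359 with centring and scaling. The lists were pooled because their signs had been seen, so the test cannot tell whether the class differs, and spot intensities, which would show it, were not used here.

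Features of at least 2-fold size with a common sign gathered in the first column of subarrays, 43 of 64 against 24.9% of all features (Fisher's exact test, two-sided, p = 1.23e-12). Neighbouring spots are not independent, so this p is too small. The ratio of a spot followed the mean of its neighbours with r = 0.424 for the turned mean, and with 0.18, 0.464, 0.288 and 0.217 on arrays 1 to 4. The SD of the log2 ratio in that column was 0.439, 0.629, 0.62 and 0.586 on arrays 1 to 4, against 0.437, 0.397, 0.546 and 0.507 in the others. Different clones of one gene, 1620 pairs, had turned ratios that correlated at 0.0287 (one-sided permutation p = 0.122).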
